A study of Arabidopsis thaliana with 4 samples.

How the data were processed

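Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done on whole Arabidopsis thaliana seedlings, roots included, that were 15 days old and had grown at 23 °C in long days. The plants were either wild type of the Col-0 strain or Col-0 plants with the 35S::LFY transgene, which drives the LEAFY (LFY) gene from a viral promoter. The same rabbit serum, raised against residues 223 to 424 of the LFY protein, was used on both genotypes, so that the Col-0 libraries served as the control. Groups came from the strain named in the labels, with 2 libraries each. Per the labels' protocols, sowing to sequencing was carried out in 2 independent rounds, so the replicate number marks a round that libraries of both genotypes share. Library dates and lanes are not given in the sources used here.

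The authors deposited the aligned reads of each library and 1 table of peaks. The genome build is TAIR9 per the submitters' processing notes. The aligner, its settings and the peak caller are not given in the sources used here. Each line of a read file holds the start and end of 1 aligned read of 32 to 42 bp. The deposited reads keep duplicates, with 7.74 to 15.1 reads per distinct position and strand on the nuclear chromosomes. In the peak table, the authors give 1 region per line with its start and size in bp. The table's 4 columns of sample and control read counts are whole counts, per the deposited read-me file, and how these counts were made is not stated. They came to 0.562 to 0.727 of the distinct reads counted here over the same regions, with a Pearson correlation of 0.947 to 0.992 across peaks. The authors' p-value columns are Benjamini-Hochberg false discovery rates (FDR), 1 for each replicate, per the read-me file, which also lists a sample and a control count for each replicate. The authors combined them into a rank product, which is deposited as a log2 value together with its rank, a score in which 1 is the strongest peak. All 1564 deposited peaks have both FDR values under 0.1, and the ranks reach 2181, so the table is a filtered part of a longer list. Overlapping and neighbouring genes, their strands and their distances from the peak centre also come from the authors' table.

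Everything else was computed from these files, with the main choices made before the data were examined. Reads of 1 library with the same 5' position and strand were collapsed to 1 distinct read, since copies without molecular identifiers are not independent molecules. A distinct read was counted in a region when the middle of a nominal 40 bp read starting at its 5' end lay inside. Library size was the number of distinct reads on chromosomes 1 to 5, and values are given as RPM, distinct reads per 1000000 of that number, as mean ± SD with n = 2 libraries. The regions were the authors' peaks and 500 bp windows that tile the nuclear chromosomes and hold at least 10 distinct reads over the 4 libraries. The contrast of 35S::LFY with Col-0 was tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, without normalization factors, and adjusted by Benjamini-Hochberg at 0.05. The adjusted p of a peak is from this fit, without the replicate number as a block, unless an alternative is named. The standard error (SE) of a log2 fold change is its size divided by the square root of the test's F statistic. A fold against peaks with 0 reads in both Col-0 libraries is given as a lower bound, computed with a floor of 3 reads over the Col-0 group. This floor leaves out the counting error of the 35S::LFY reads, so the exact 95% lower bound of such a peak is smaller. With 1 to 3 Col-0 reads, or where stated, the ratio of pooled rates is given with its exact 95% counting interval. All intervals and floors cover counting error only.

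The fits were tested on simulated data, drawn with a fixed dispersion and no effect of the round. Each region's mean rate over the 4 libraries was the Col-0 level, so simulated Col-0 peaks held more reads than the real ones. The real Col-0 medians were 0 and 1 reads per peak. The shares below therefore do not give the power or the error rate in the real peaks. In the peaks, 68.7% of changes of 4-fold and 100% of changes of 16-fold were recovered, with 6 false calls among 1364 unchanged peaks. In the windows, 0% of changes of 4-fold, 76.1% of changes of 16-fold and 0% of falls to 0.25 were recovered, with 0 false calls among 110227 unchanged windows. As a check of the pairing that the labels give, deviations from the group means of same-numbered libraries correlated at 0.169 across peaks and 0.109 across windows.

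Genes were linked to a peak when its centre lay within the gene, up to 3000 bp upstream of its start or up to 1000 bp downstream of its end, using the authors' neighbouring genes and distances only. A centre within a transcript but in no annotated exon was taken as intronic, and 8 neighbours without a strand were linked within 1000 bp. Of the 3061 locus names in the authors' columns, 2995 matched the reference table of the TAIR10.1 assembly, which gave symbols, the set of 27444 nuclear protein-coding genes and, at the peak of rank 1, the order of genes. None of its coordinates are given or compared with those of the peaks. The 12 gene lists and LFY itself, 285 genes in all, had been written down beforehand, and each list was compared with the other protein-coding genes by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment over the 12 lists. The named genes are LFY, every listed known or proposed LFY target, the genes next to the 10 peaks with the largest fitted fold change among those past the threshold and higher in both replicate pairs, and from each other list up to 4 members with the largest fold change of their best peak. Peaks with 0 Col-0 reads have large fitted fold changes, so this rule can leave out better-ranked peaks, such as that of the immunity gene BAK1 (rank 40). Windows past the threshold outside the peaks were to be named by their nearest gene, and are given by position because no TAIR9 gene annotation was used here. For the same reason the planned comparison of promoter shares with the whole genome was replaced by a two-sided exact binomial test of peaks upstream against peaks downstream of genes, and the exon to intron density at LFY and all analyses of the DNA sequence of peaks are not analysed here. Alternatives were all reads as deposited, scaling on 10 kb bins outside peaks, edgeR's TMM factors, other count minimums, DESeq2 1.42.0, the replicate number as a block, leaving out each library, other region sizes and, for genes and promoters, other distances. Peak counts of the authors' table, a background of genes with a symbol and all reads around LFY were added after seeing the data. Tests across peaks and lists used scipy 1.17.1 and statsmodels 0.14.6.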

Results

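LFY is a plant transcription factor that sets floral meristem identity, and the study mapped where it binds the genome of seedlings that overproduce it. Immunoprecipitated DNA of 2 35S::LFY and 2 Col-0 libraries was compared. The Col-0 libraries held 3992835 and 7746028 aligned reads, and the 35S::LFY libraries 5798319 and 19893590. After collapsing copies, 259925 and 391148 distinct nuclear reads remained in Col-0 replicates 1 and 2, and 392445 and 2381344 in 35S::LFY replicates 1 and 2. Read density was therefore 2.18 and 3.28 distinct reads per kb in Col-0, and 3.29 and 19.99 in 35S::LFY, so 35S::LFY replicate 2 gives the most precise values. Chloroplast reads made up 1.16% and 34.2% of the reads of Col-0 replicates 1 and 2, and 0.408% and 6.90% in 35S::LFY.

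The LFY locus itself (AT5G61850, chromosome 5) was compared first, because the genotypes differ in this gene. The authors' table places a peak of rank 1269 in an intron of LFY, at positions 24846024 to 24846252 of TAIR9. It held 47.5 ± 5.89 RPM (SD, n = 2) in 35S::LFY and 3 distinct reads in the Col-0 libraries together. The ratio was 11.0 with a counting interval of 3.67 to 53.8. The peak passed the edgeR test at an adjusted p of 0.000114, and at 0.0486 with the replicate block. The adjusted p was 0.161 without 35S::LFY replicate 1, 0.290 without 35S::LFY replicate 2 and 0.242 with all reads as deposited, and lay between 1.73e-05 and 0.967 over all alternatives. Between the neighbouring genes AT5G61840 and AT5G61865, outside the peak, RPM per kb were 17.9 and 9.91 in Col-0 and 22.7 and 35.2 in 35S::LFY, against a mean of 8.39 over the nuclear genome in each library. The pooled ratio was 2.55 with a counting interval of 1.87 to 3.56. The difference has an exact two-sided permutation p of 0.333, the smallest that 2 against 2 libraries can give. Whether LFY copies in the transgene add reads at this locus was not tested. The ratio of 11.0 in the peak therefore does not by itself show binding of LFY to its own gene.

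All 1564 authors' peaks carried more reads in 35S::LFY than in Col-0, in both replicate pairs. Peaks held 12.8% (Wilson 95% interval 12.7 to 12.9) and 10.8% (10.8 to 10.9) of the distinct reads of 35S::LFY replicates 1 and 2. In Col-0 they held 0.287% (0.268 to 0.309) and 0.745% (0.718 to 0.772). The pooled rate in 35S::LFY exceeded that in Col-0 44.5-fold in replicate 1 (counting interval 41.4 to 47.9) and 14.5-fold in replicate 2 (14.02 to 15.1). Per peak, the median pooled fold was 15.0 and the range 4.07 to 195, with the 342 peaks that had 0 Col-0 reads set to their lower bound. The plot of reads around peak centres shows this enrichment close to the centre.

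**Figure D1:**
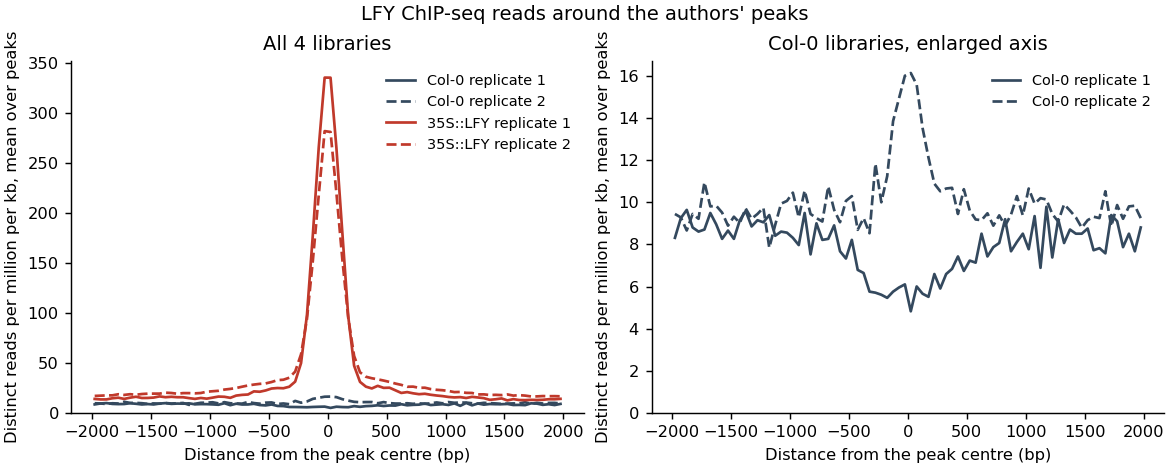
Mean RPM per kb in 50 bp bins against the distance from the centre of the 1564 authors' peaks, for all 4 libraries (left) and for the Col-0 libraries on an enlarged axis (right). Both 35S::LFY lines rise at the centre; of the Col-0 lines, replicate 2 rises and replicate 1 dips.

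In the edgeR test 1564 of 1564 peaks were higher in 35S::LFY and 0 lower, with the largest adjusted p at 0.00520. The peaks had been selected by the authors on these libraries, so the count shows how far the list holds in a joint test and is not independent evidence of binding. It fell to 30 without 35S::LFY replicate 1, to 360 without 35S::LFY replicate 2 and to 594 with all reads as deposited, while the median fitted log2 fold change, 4.50 with all libraries, was 4.45, 4.50 and 5.52. With TMM factors, which assume that most regions do not differ, the median was 0.93 and the count 0 (96 higher and 1 lower at an unadjusted p under 0.05). With the replicate block 1375 passed, with the largest adjusted p at 0.138, and DESeq2 called 1558. The fitted folds depend on Col-0 replicate 2: without it 1110 peaks had 0 Col-0 reads and the median was 8.49, which depends on the prior count and is no bound. With peaks at 0 Col-0 reads set to their lower bound, the median ratio of 15.0 became 6.11 without Col-0 replicate 2 and 9.61 without Col-0 replicate 1. The value of 6.11 is set by the bound, at which 1110 of the 1564 peaks then stood, and is no measured ratio. Without Col-0 replicate 1 it was 461 peaks, and 342 with all libraries. The bound is lower when fewer Col-0 reads remain in total.

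The authors' strongest peaks are described next, chosen after their values were seen. The peak of rank 1 lay on chromosome 5 at 1021678 to 1022135, downstream of both AT5G03830 and AT5G03837. In the TAIR10.1 table the protein-coding gene after AT5G03830 is TFL1, the shoot identity gene that represses flowering and is a proposed LFY target. This peak held 174 and 579 reads in 35S::LFY and 2 in each Col-0 library. Its log2 fold change was 5.75 (SE 1.3), with an edgeR adjusted p of 1.79e-05, or 0.0157 with the replicate block. Rank 2 lay on chromosome 3 at 18706710 to 18707162, 365 bp from the end of AT3G50400 and 2812 bp upstream of OBP1, and rank 4 between the flowering repressors MAF3 and MAF4 on chromosome 5 at 25991796 to 25992161, 281 bp upstream of MAF4. Rank 3 (10713547 to 10714151 on chromosome 1), between AT1G30350 and ERD4 and upstream of both, had a ratio of 195, with a counting interval of 35.0 to 7723, from 1 Col-0 read.

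By the fixed rule, 10 peaks with the largest fitted fold change were singled out, each with 0 reads in both Col-0 libraries. At 0 Col-0 reads this fold depends on the prior count, so the rule need not pick the most enriched peaks. Their ranks by the authors ran from 34 to 121, and the peak of rank 3, with a ratio of 195, was not among them. The 10 peaks were at least 26.0 to 31.8-fold higher in 35S::LFY. Their adjusted p lay between 1.26e-06 and 1.59e-06 in edgeR, and was 0.0133 with the replicate block. Their genes include RD26, a drought-responsive NAC factor, whose 5' UTR held the centre of a peak (chromosome 4, 13708784 to 13709285) with 147 ± 1.17 RPM (SD, n = 2). WRKY3 had a peak 978 bp upstream (chromosome 2, 1017974 to 1018280) at 169 ± 63.2 RPM. Others were LSH3 (1113 bp upstream, 167 ± 63.4 RPM), OFP16 (815 bp upstream, 155 ± 47.2 RPM), the sugar transporter gene TMT3 (411 bp upstream and 160 bp upstream of AT3G51500, 188 ± 91.1 RPM), BCA6 (109 bp upstream, 151 ± 31.96 RPM) and A/N-InvF (193 bp downstream, 178 ± 90.4 RPM). The remaining 3 lay 117 bp upstream of AT4G03450 (211 ± 148 RPM), 140 bp upstream of AT3G27340 (195 ± 109.9 RPM) and in the coding sequence of AT1G01180 (151 ± 60.9 RPM). Without 35S::LFY replicate 1, 1 of the 10 passed the threshold, and without 35S::LFY replicate 2 all 10 did.

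Of 14 known or proposed LFY targets, 6 had a peak, with 9 peaks among them. All 9 were higher in 35S::LFY, as were all 1564 authors' peaks, which had been selected on these libraries. With the replicate block the edgeR adjusted p of the 9 peaks lay between 0.0133 and 0.0923. AP1, a floral meristem identity gene, had the peak of rank 19, 289 bp upstream of its start (chromosome 1, 25986344 to 25986861). It held 292.5 ± 127 RPM in 35S::LFY and 11.5 ± 5.41 in Col-0. The log2 fold change was 4.57 (SE 1.13, edgeR adjusted p = 6.35e-05, or 0.0184 with the replicate block). A second peak in an AP1 intron (25984894 to 25985137) held 43.7 ± 3.04 RPM against 1 Col-0 read, a ratio of 27.5 (4.83 to 1094). SEP3, another floral MADS-box gene, had a peak 2624 bp upstream on chromosome 1 (8598377 to 8599068) with 232 ± 33.1 RPM against 15.4 ± 0.0351, a log2 fold change of 3.91 (SE 1.03). AG, which specifies stamens and carpels, had an intronic peak on chromosome 4 (10386519 to 10386810) with 64.1 ± 11.4 RPM against 6.40 ± 1.83, a log2 fold change of 3.39 (SE 0.84).

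LMI2, a MYB gene, had peaks 542 and 938 bp upstream on chromosome 3. The nearer one rose by 3.76 on the log2 scale (SE 0.85), and the farther one, at 0 Col-0 reads, was at least 16.1-fold higher. RAX1, a MYB gene of axillary meristems, had a peak 686 bp upstream (104 ± 25.6 RPM against 8.96 ± 1.79) and one in its coding sequence, where the log2 fold change was 2.29 (SE 0.74) and the adjusted p of 0.00201 became 0.0923 with the replicate block and lay between 0.000401 and 0.509 over all alternatives. ELA1, a cytochrome P450 gene, had a peak 236 bp upstream with 112 ± 28.7 RPM and 2 Col-0 reads, a ratio of 31.8 (8.72 to 264). CAL, PI, TFL1, LMI1, UFO, ELA2 and FLS2 were next to no peak in the authors' table, and the peak next to AP3 lay 2010 bp beyond the gene's end, outside the limit. Also outside the limit were a further peak of SEP3, 4257 bp upstream, and a further peak of RAX1, 1735 bp downstream. For TFL1, the authors' columns name only AT5G03830 and AT5G03837 at the peak of rank 1. TFL1 was therefore counted without a peak, although it follows AT5G03830 among the protein-coding genes. Its distance from that peak was not measured. Without 35S::LFY replicate 1, 2 of the 9 peaks passed the threshold, without 35S::LFY replicate 2 it was 3, and with all reads as deposited 6.

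**Figure D2:**
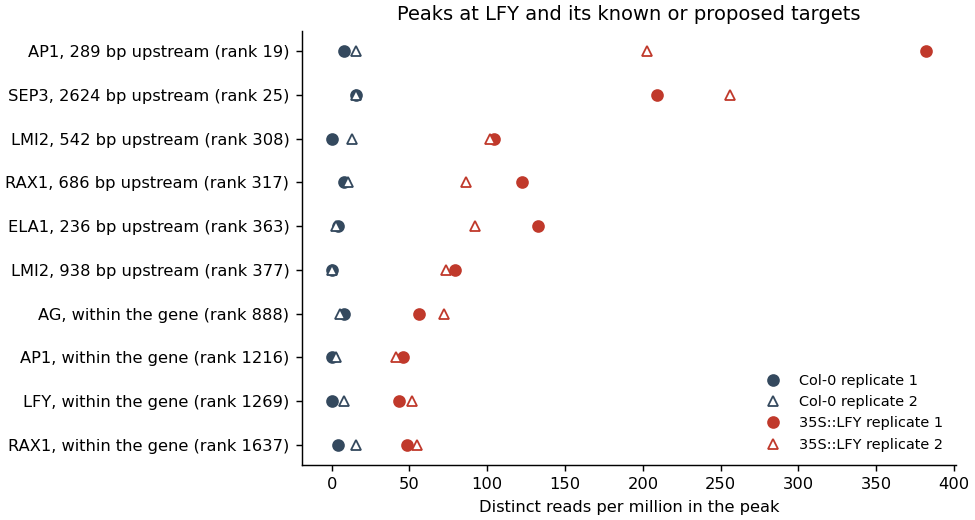
Distinct reads in each peak, as RPM, at LFY and at its known or proposed targets, 1 point per library (filled circles replicate 1, open triangles replicate 2, red 35S::LFY, dark Col-0). At every peak both 35S::LFY points lie above both Col-0 points, with AP1 reaching 382 and 203. The authors had selected the peaks on these same libraries.

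**Figure D3:**
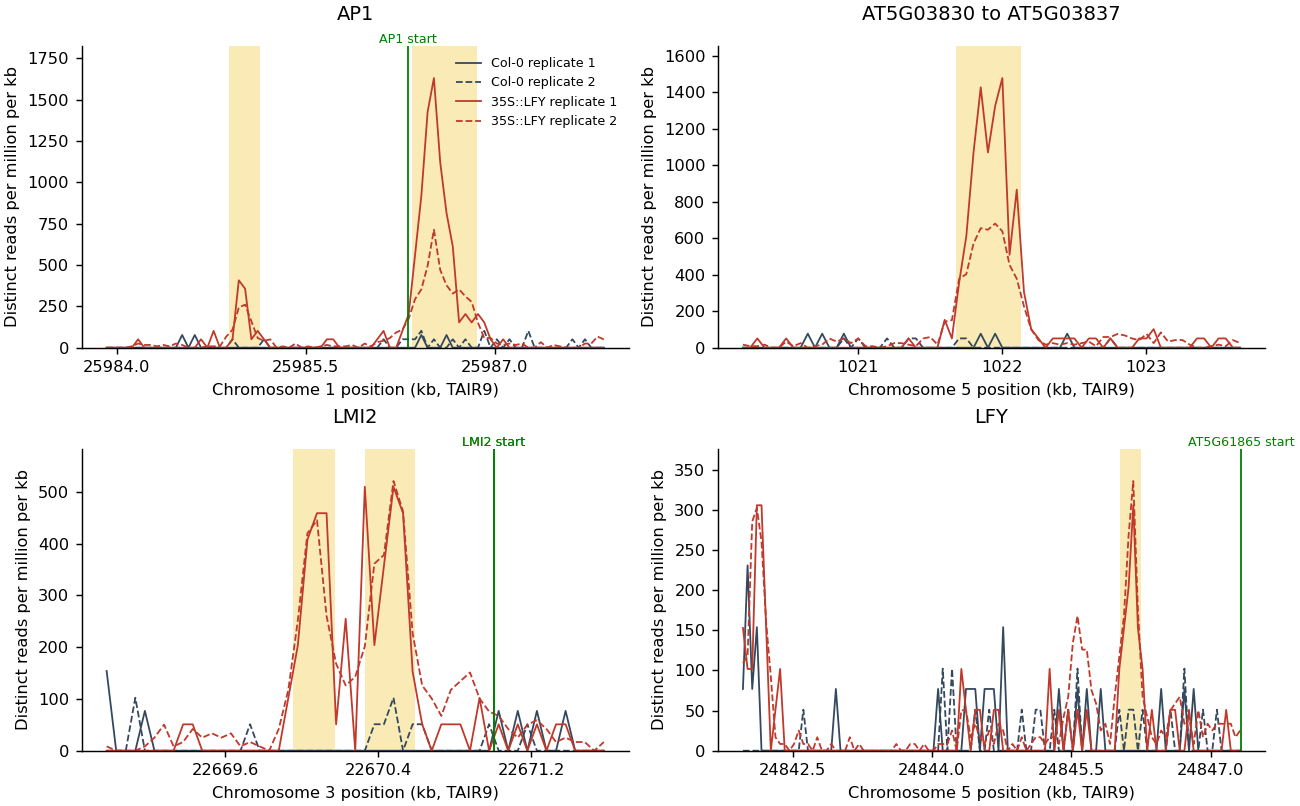
RPM per kb in 50 bp bins along TAIR9 positions at AP1, at the peak of rank 1, at LMI2 and at LFY; yellow bands are authors' peaks and green lines gene starts computed from the authors' distances. At LFY, reads of both 35S::LFY libraries and of Col-0 replicate 1 also gather at the left end of the interval, outside the peak.

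As a group, the 14 targets had a peak more often than other protein-coding genes, 42.9% (exact 95% interval 17.7 to 71.1) against 7.53% (Fisher's exact test, odds ratio 9.21, adjusted p = 0.00389). Some of these targets were proposed from LFY ChIP data, which can include these libraries, so the share is not independent evidence. In the wider list of floral organ identity and development 4 of 20 genes had a peak (adjusted p = 0.118). The 4 were AP1, AG, SEP3 and SEP4, whose intronic peak (chromosome 2, 1130062 to 1130345) held 41.0 ± 0.271 RPM and was at least 8.92-fold higher.

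Of 27 flowering time genes, 4 had a peak, which did not pass the test (14.8%, adjusted p = 0.190). TEM1, a repressor of flowering, had the peak of rank 6, 881 bp upstream on chromosome 1 (8983680 to 8984166), with 289 ± 81.7 RPM and 2 Col-0 reads, a ratio of 80.5 (22.2 to 666). FD and FDP, bZIP genes, had peaks 2408 and 2040 bp upstream with 106 ± 1.14 and 100.3 ± 13.04 RPM and ratios of 68.8 (12.2 to 2726) and 20.3 (6.88 to 99.3). FLM, a MADS-box repressor, had a peak 193 bp upstream that was at least 9.39-fold higher. Of 26 genes of the shoot meristem and organ polarity 4 had a peak (15.4%, adjusted p = 0.190), namely ANT (912 bp upstream, at least 15.9-fold higher), CLV1 (807 bp upstream, ratio 25.1, 4.41 to 1001), KAN1 (2799 bp upstream, ratio 18.3, 4.98 to 153) and AIL6 (intron, ratio 20.9, 3.65 to 834). Without 35S::LFY replicate 1 the best peaks of 1 of these 4 flowering time genes and 0 of these 4 meristem genes passed, and without 35S::LFY replicate 2 those of 3 and 2.

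Genes of cytokinin and gibberellin carried peaks more often than other genes. Of 28 cytokinin genes 8 had a peak (28.6%, 13.2 to 48.7, adjusted p = 0.00492). Among them were the type-A response regulators ARR8 and ARR9, with peaks 1426 and 1315 bp upstream at least 9.15 and 9.55-fold higher, and ARR3, with a peak 886 bp downstream at a ratio of 25.8 (4.54 to 1029). The receptor gene AHK3 had a peak 238 bp downstream with 155 ± 19.1 RPM against 6.40 ± 1.83, a log2 fold change of 4.60 (SE 1.01). Of 28 gibberellin genes 7 had a peak (25%, 10.7 to 44.9, adjusted p = 0.0159). The biosynthesis gene GA3OX2 (1268 bp upstream) was at least 14.5-fold higher and the catabolic gene GA2OX2 (coding sequence) at least 8.06-fold. The receptor gene GID1B had 3 peaks, the strongest 2294 bp upstream with a ratio of 59.6 (10.6 to 2364), and ELA1 stands on this list as well as among the targets. With peaks limited to 1000 bp upstream to the gene end, adjusted p was 0.105 for cytokinin and 0.426 for gibberellin, with the better-ranked 782 peaks it was 0.184 and 0.393, and with nearest genes only 0.00891 for both. Without 35S::LFY replicate 1 the best peaks of 0 of the 8 genes named from these lists passed, and without 35S::LFY replicate 2 those of 1 cytokinin and 2 gibberellin genes.

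Of 36 auxin genes 6 had a peak (16.7%, adjusted p = 0.118, but 0.0246 when only the nearest gene of a peak was counted, and up to 0.659 over the alternatives). The efflux carrier gene PIN4 (intron), the influx carrier gene AUX1 (668 bp downstream) and IAA17 (1895 bp upstream) were at least 18.8, 15.7 and 7.20-fold higher, and the receptor gene TIR1 (2720 bp upstream) had a ratio of 25.5 (8.65 to 124). Immunity genes had peaks in 5 of 38 cases (13.2%, adjusted p = 0.247). Among them RPS2, an immune receptor gene, had a ratio of 75.3 (13.4 to 2985) 900 bp upstream and MLO2 27.7 (4.88 to 1103), while PEN2 and RBOHF were at least 6.57 and 6.26-fold higher. FLS2 had none. Light signalling genes had peaks in 4 of 22 cases (18.2%, adjusted p = 0.136). HFR1 (281 bp downstream) was at least 11.1-fold higher, and PIF7, ATHB4 and PAR1 had ratios of 43.4 (7.70 to 1724), 35.4 (9.73 to 294) and 36.6 (6.48 to 1455). Of the 4 genes named from each of these 3 lists, the best peaks of 0 passed without 35S::LFY replicate 1, and without 35S::LFY replicate 2 those of 2 auxin, 1 immunity and 1 light signalling gene.

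The photosynthesis genes, a list meant for comparison, also had peaks more often than other genes. Of 26 nuclear photosynthesis genes 6 had a peak (23.1%, 8.97 to 43.65, adjusted p = 0.0341, and between 0.0670 and 0.105 under the alternatives), among them LHCA1 (842 bp downstream, at least 12.6-fold higher) and the near-identical LHCB1.1, LHCB1.2 and LHCB1.3, for which the origin of the reads is uncertain and of which LHCB1.1 and LHCB1.3 share a peak. Reference genes had peaks in 2 of 15 cases, ACT7 (130 bp upstream, ratio 13.3, 4.47 to 65.1) and TUB6 (208 bp upstream, log2 fold change 3.96, SE 0.96), with an adjusted p of 0.343. Root identity genes had 1 of 15, CPC (2055 bp upstream, ratio 43.0, 7.61 to 1706, adjusted p = 1). Of the 6 peaks named in these lists, 0 passed without 35S::LFY replicate 1 and 2 without 35S::LFY replicate 2. Genes with a symbol had peaks more often than all genes, 9.57% against 7.53% of the genes outside the target list. Against this background, chosen after seeing the data, adjusted p was 0.0143 for LFY targets, 0.0231 for cytokinin, 0.0582 for gibberellin and 0.101 for photosynthesis.

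**Figure D4:**
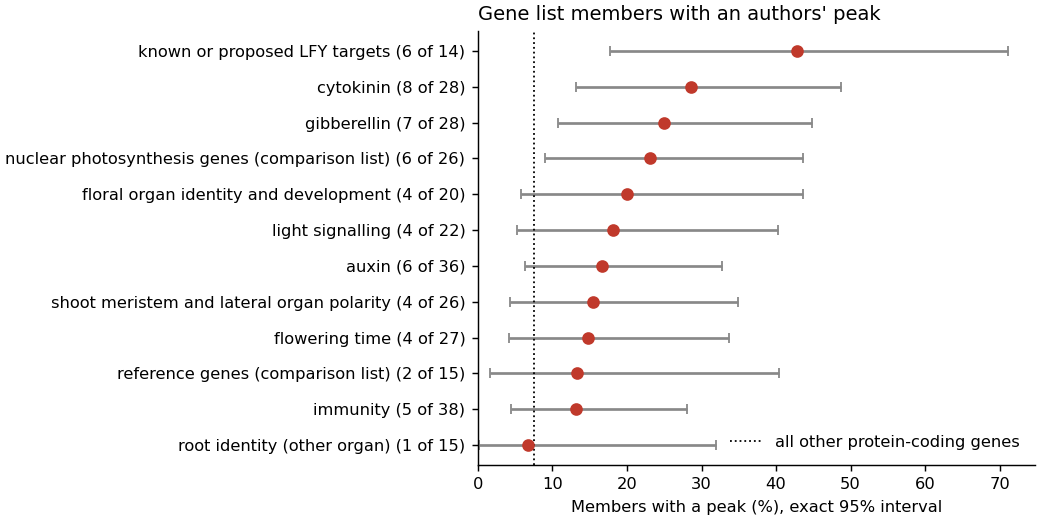
Percentage of the members of each of the 12 gene lists with an authors' peak, with the exact 95% binomial interval; the dotted line is the percentage among other protein-coding genes. The known or proposed LFY targets lie highest at 42.9%, and the interval of the photosynthesis comparison list, 8.97 to 43.65, also lies above the line.

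Most peaks lay between genes. By the authors' annotation of peak centres, 1170 of 1564 (74.8%, 72.6 to 76.9) were intergenic, 156 in coding sequence, 88 in 5' UTRs, 78 in introns and 61 in 3' UTRs. Of all peaks, 42.1% (39.7 to 44.6) were intergenic and lay within 1000 bp upstream of a gene start. Another count, 25.2%, were intergenic and lay within 1000 bp downstream of a gene end, and a peak can be in both. Peaks inside a gene were not counted here, however near a neighbouring gene. Intergenic peaks with only an upstream gene in that range outnumbered those with only a downstream gene 456 to 191 (exact binomial test, p = 6.22e-26). The test takes both sides as equally likely. How much of the genome lies on each side of genes was not measured, so the p does not show a preference of LFY for promoters. Of the intergenic peaks, 447 lay between divergent genes, upstream of both, and 102 between convergent genes. The nearest gene start upstream of which an intergenic peak lay was at a median distance of 679.5 bp (quartiles 198.8 and 1696).

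The windows give a comparison that does not use the authors' list. Of 110427 windows, 1304 were higher in 35S::LFY and 15 lower, and 1080 of the higher windows (82.8%) overlapped a peak, against 2.29% of all tested windows. They covered 981 of the 1564 peaks. The authors had selected their peaks on these same libraries, so the overlap is not independent evidence of binding. With the replicate block 0 windows passed in either direction (5363 higher and 1267 lower at an unadjusted p under 0.05, edgeR). The count of higher windows was also 0 without 35S::LFY replicate 1 and without 35S::LFY replicate 2 (1212 and 1640 at an unadjusted p under 0.05), 485 without Col-0 replicate 1, 543 without Col-0 replicate 2, 283 with all reads as deposited, 402 with TMM factors, 819 without the read minimum, 2153 with 200 bp windows and 3017 in DESeq2, which gave no adjusted p for 94201 of the windows and so adjusted over fewer of them. Scaling on bins outside the peaks moved the median log2 fold change of all windows to 0.44 and TMM moved it to 0.46, and the fold changes given are relative to library size.

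Of the higher windows, 224 lay outside the peaks, 196 of them over 1 kb from the nearest peak centre. The 5 with the largest fitted fold change had 0 Col-0 reads. The window at 19791501 to 19792000 on chromosome 3 was at least 14.2-fold higher, that at 1021001 to 1021500 on chromosome 2 at least 15.0-fold, that at 1479001 to 1479500 on chromosome 3 at least 13.8-fold, that at 8114001 to 8114500 on chromosome 1 at least 13.9-fold and that at 16559501 to 16560000 on chromosome 4 at least 13.1-fold. None of the 15 lower windows overlapped a peak. They rested on 10 to 13 Col-0 reads each and on 0 or 1 in 35S::LFY, and the window at 2909001 to 2909500 on chromosome 2, with 13 against 0, had the largest fitted change. The count of lower windows was 0 without Col-0 replicate 1, 1 without Col-0 replicate 2, 0 without 35S::LFY replicate 1 or replicate 2 (1307, 1685 and 1157 at an unadjusted p under 0.05 in the 3 fits with 0) and 171 in DESeq2, with the same 94201 windows left without an adjusted p.

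Across the 1564 peaks, which are not independent replicates, reads of the 35S::LFY libraries were related between replicates (Spearman rho 0.725), and those of the Col-0 libraries hardly (0.0709). The log2 ratio of 35S::LFY over Col-0 was weakly related between the replicate pairs (rho 0.230, bootstrap 95% interval 0.180 to 0.274). It was 0.591 with a pseudocount of 5 reads, -0.0252 with all reads as deposited and -0.0228 in the better-ranked 782 peaks. The median peak held 0 reads in Col-0 replicate 1, 1 in Col-0 replicate 2, 24 in 35S::LFY replicate 1 and 147 in 35S::LFY replicate 2.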

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

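Peak counts of the authors' table, all reads around LFY and the background of genes with a symbol were tried only after the data had been seen. The 1564 peaks higher in 35S::LFY became 594 with all reads as deposited and 0 with TMM factors (96 higher at an unadjusted p under 0.05), where the median log2 fold change went from 4.50 to 0.93. Scaling on outside bins, the minimum of 20 reads, DESeq2, the narrower region and the authors' counts gave 1558 to 1564. Leaving out 1 library gave 30 to 1562, with a median fitted log2 fold change of 4.19 to 8.49, the highest without Col-0 replicate 2. The low end came without a 35S::LFY replicate, when the spread is taken from the Col-0 pair alone and the lone library is assumed to vary like it. With the replicate block, which the labels' 2 rounds justify, 1375 peaks, 0 higher windows and 0 lower windows passed (5363 and 1267 windows at an unadjusted p under 0.05).

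The 1304 higher windows became 283 with all reads, 402 with TMM, 819 without a minimum, 3017 in DESeq2 and 2153 at 200 bp, and 0 to 543 with 1 library left out. Scaling on outside bins kept the count within 1.5 times. The 15 lower windows became 0 with all reads and 0 with TMM (2309 and 689 at an unadjusted p under 0.05), 7 with outside bins, 2 without a minimum, 171 in DESeq2 and 5 at 200 bp, and 0 to 1 with 1 library left out. DESeq2 gave no adjusted p for 94201 windows. The cause of these changes was not tested.

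The replicate correlation of 0.230 became -0.0252 with all reads, 0.591 with a pseudocount of 5 and -0.0228 in the better-ranked peaks, and the cause was not tested, apart from saturation. The excess of upstream over downstream peaks held for promoters of 500 and 3000 bp and for the better-ranked peaks. Of the 12 lists, 4 passed the test, 1 with the gene range of 1000 bp upstream to the gene end, 1 with the better-ranked peaks, 2 with the symbol background and 4 with nearest genes only, and the cause was not tested. The list of LFY targets passed in each of these settings.

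Of 54 named peaks, 53 passed with the block (all but the RAX1 peak in coding sequence), 41 with all reads, 4 without 35S::LFY replicate 1, 26 without 35S::LFY replicate 2 and 54 without either Col-0 replicate. TMM, which lowered the peaks as a whole, put the 4 with the smallest log2 fold changes below 0: LFY (-0.21), AG (-0.22) and the 2 RAX1 peaks (-0.18 and -1.32). This shows their rank among the named peaks and not a lower level than in Col-0. The ratio around LFY outside its peak was 2.55 for distinct reads and 2.00 for all reads. Core motif shares, the matrix AUC and the score correlation, with their alternatives, and the exon to intron density at LFY were not run. Depth limits the folds of the 342 peaks with 0 Col-0 reads to lower bounds.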

Other observations

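The tests of gene families and the test with a constant in place of the Col-0 counts were chosen only after the data had been seen. Among 148 families of 10 or more protein-coding genes that share a symbol stem, 3 had a peak more often than other genes (Fisher's exact test, Benjamini-Hochberg adjusted). Of 22 genes named ERF, most of them ethylene response factors, 7 had a peak (31.8%, adjusted p = 0.0422). ERF2, ERF4 and ERF5 had theirs 97, 99 and 200 bp upstream, with ratios of 65.5 (11.7 to 2596), 14.6 (3.94 to 122) and 20.03 (6.78 to 97.8). ERF15 had a ratio of 27.9 (9.45 to 136), and ERF38, with 0 Col-0 reads, was at least 13.8-fold higher. ERF3 and ERF8 had the lowest ratios, 5.93 (2.24 to 22.2) and 4.81 (2.15 to 13.4). The other stems were CAT (5 of 11, with 4 peaks, since CAT1 and CAT3 share one and were counted as separate genes), which mixes catalases and amino acid transporters, and PDE (6 of 16), a name for pigment mutants; both had an adjusted p of 0.0422, and CAT 0.228 with nearest genes only. NAC genes had a peak in 14 of 79 cases, with 13 peaks (NAC050 and NAC052 share one; adjusted p = 0.0651, and 0.0416 with nearest genes only). Against genes with a symbol, the adjusted p was 0.157 for ERF, PDE and CAT and 0.382 for NAC.

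Several genes outside the lists had 3 peaks each, the most of any gene, including the transcription factor gene LBD37, BBX28, the aquaporin gene PIP3, the expansin gene EXPA8 and SAUR63. Of 2071 protein-coding genes with a peak, 161 had 2 or more. These genes were picked for their number of peaks, and no test was made of it.

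Col-0 replicate 2 held more reads at the peaks than beside them, 1.65 times the level 2 to 4 kb away (bootstrap 95% interval 1.55 to 1.77), whereas Col-0 replicate 1 held fewer, 0.655 times (0.581 to 0.726). Carry-over of sequenced 35S::LFY replicate 2 reads is argued against: the positions they share within peaks exceeded those after shifts of 3 to 10 bp by 1.68 percentage points (SE 0.873; 33.3% against 31.6%), where the separate libraries of 35S::LFY replicates 1 and 2 gave 1.93. The dip in replicate 1 may come from the selection of peaks with few control reads. At 1000 windows chosen from the 35S::LFY libraries alone, 800 of which overlap peaks, its ratio was 1.19 with bounds of 0.906 and 1.59, and that of replicate 2 was 2.00 (1.83 to 2.199). Whether LFY made by Col-0 plants adds to the signal stays open, since the value of 1.19 in replicate 1 allows both no rise and a small one, and chromatin mixed before amplification was not tested.

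The log2 ratios of the peaks were only weakly related between replicates. In 35S::LFY replicate 2 reads filled up to 63.2% of the positions of a peak, and saturation was tested with a correction that assumes evenly spread reads. It gave a rho of 0.279, which argues against saturation of that kind as the only reason. Reads gather near the peak centre, and the few Col-0 reads may also limit this rho, so a part played by saturation stays open. Whether the few Col-0 reads per peak are the reason stays open. With a constant in place of the Col-0 counts rho was 0.725, but this ratio ranks the peaks by their 35S::LFY reads alone, so the value is by construction the rho of those reads (0.570 in the better-ranked peaks) and decides nothing. No biological explanation was tested.

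The 196 called windows over 1 kb from the peaks held a median of 28.0 and 43.5 RPM in the 35S::LFY libraries, and 137 of them had 0 Col-0 reads. The mean over all tested windows was 7.03 and 7.83 RPM. Windows were called for high 35S::LFY and low Col-0 reads, so these levels follow from the call and are not evidence of binding. The most frequent distance from plus to minus strand reads was 140 bp in the 196 called windows and in the authors' peaks, a difference of 0 bp (bootstrap interval -23 to 3). Other tested windows had 112 bp, which also lies within the margin of 30 bp set for the test, so the distance does not decide. Piles of reads without the strand pattern of immunoprecipitated fragments therefore stay open, and LFY binding that missed the authors' threshold was not tested.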
